A study of Mus musculus with 8 samples.

How the data were processed

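Kidneys of 8 mouse embryos at E14.5 (E, embryonic day) were measured on 1-colour arrays, 4 embryos with a knockout of Grb2 in the ureteric bud epithelium (Grb2_cKO) and 4 wild-type controls. Per the labels' protocols, both kidneys of an embryo were pooled, total RNA was extracted with a micro-scale column kit, and 200 ng of it was amplified with an Ambion WT kit and labelled with biotin. Per the series' design text, all embryos came from 1 litter, so each array stands for a separate animal. Replicate numbers were given in the order of the samples' records and pair nothing between the groups.

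The values used are log2 probe-set values of 41345 probe sets, processed by the authors before they were deposited. The submitters' processing notes name the Transcriptome Analysis Console, with no version. The background correction, summarization and normalization between arrays are not given in the sources used here. That the deposited values are on the log2 scale was read from the values: they ran from 1.25 to 14.08, with array medians from 6.61 to 6.72. No value was transformed or normalized again. No detection calls, scan dates or other batch records were used here, so a batch could not be tested, and a probe set near background could not be told from an expressed one. The precision of array values is limited by the number of arrays.

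Probe sets were named through the platform's annotation, with symbols updated through the Entrez gene identifier to those of the GRCm38.p6 RefSeq gene table for 23328 of them. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and were not named, and 16010 had none in the annotation used here. For the 1082 genes with more than 1 probe set, the one with the highest mean over all 8 arrays stood for the gene, which left 22180 genes. The RefSeq table also gave which genes lie between Dlk1 and Dio3. No coordinates are given, since the build behind the annotation is not given in the sources used here.

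Grb2_cKO was compared with control in limma 3.58.1 (R 4.3.3), with a linear model and empirical Bayes moderation on all 8 arrays and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all 22180 genes, with a threshold of 0.05. Adjusted p-values of genes in the text come from this model unless another is named. Log2 fold changes are Grb2_cKO minus control, with the moderated standard error (SE) of the model, and group values are means ± SD of 4 embryos. For Grb2 and for gene list scores, a two-sided exact permutation test over the 70 assignments of 4 of 8 embryos was added. Its smallest possible p is 0.0286.

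For gene groups, 27 lists of markers and pathway genes were tested with limma's camera, with its preset correlation of 0.01 between genes, and adjusted by Benjamini-Hochberg over the 27 lists. Of 509 genes on these lists and the sex-linked list, 443 were measured and the others were not analysed here. Camera asks whether a list shifted relative to all other genes. The same test with a correlation estimated for each list, fry and the permutation of list scores were run as alternatives. Fry and the permutation ask whether a list shifted at all, not whether it shifted more than other genes. A list score is the mean over members of an embryo's value minus the gene's mean over all 8 embryos. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list.

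The groups, the model, the lists, the named genes and most alternatives were fixed before the data were examined. Genes named were Grb2, the 12 largest positive and 12 largest negative log2 fold changes among genes past the threshold whose groups did not overlap, up to 4 members of smallest p per list, a panel of 16 kidney genes and the sex-linked genes. From the largest changes, predicted genes, small RNA genes, receptor clusters and ribosomal protein genes were left out by name. Of the panel, 1 gene is not reported here. Other genes are marked as chosen after their values were seen.

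The alternatives were quantile normalization, centring on array medians, leaving out the dimmest genes, the mean of a gene's probe sets, a trended and robust spread, array weights, other thresholds, all probe sets, the mean of the Y-linked genes or of the erythroid list as a covariate, and leaving out each embryo in turn. Using control replicate 3 as the only control, and leaving out genes on the X and Y chromosomes, were added after seeing the data. The model was tested on simulated data for 22180 genes, 4 and 4 arrays and 200 changed genes in each of 20 draws. It recovered 61.6% of simulated log2 changes of 0.5 and 98.4% of those of 1, with 8.45 false calls per draw. The simulated genes varied independently of each other and the simulated groups did not differ in sex. The number of false calls therefore does not carry over to the real comparison.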

Results

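RNA of whole embryonic kidneys was compared between 4 Grb2_cKO and 4 control embryos of 1 litter at E14.5. GRB2 is an adaptor protein that links receptor tyrosine kinases such as RET to the RAS and ERK pathway. RET in the tips of the ureteric bud, with its co-receptor GFRA1, receives GDNF from the surrounding mesenchyme and drives branching of the bud. The comparison asks how loss of Grb2 in the ureteric epithelium changes the transcriptome of the developing kidney. The arrays had medians of 6.61 to 6.72 on the log2 scale, and their number limits the precision. Across genes, Pearson's r was 0.992 to 0.996 between controls, 0.991 to 0.994 between Grb2_cKO embryos and 0.975 to 0.989 between the groups. Genes are not independent replicates. No arrays held identical values.

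Grb2 itself was lower in all 4 Grb2_cKO kidneys, at 8.20 ± 0.12 against 8.65 ± 0.03 in controls (SD, n = 4 each). The log2 fold change was -0.45 (SE 0.07, 95% interval -0.61 to -0.28), which leaves 73.3% of the control level (65.4% to 82.3%), with an adjusted p of 0.0017 and an exact permutation p of 0.0286, the smallest the design allows. The deletion was confined by design to the ureteric epithelium, and the RNA came from all cells of the kidney. Which part of the transcript the single Grb2 probe set reads, relative to the deleted part, is not given in the sources used here. With the mean of the Y-linked genes as a covariate the log2 fold change was -0.40 (adjusted p = 0.10).

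Genes of the ureteric bud tip and of the GDNF and RET signal were among the largest falls. Slco4c1, an organic anion transporter gene of the tip list, fell 13.6-fold (log2 fold change -3.76, SE 0.18), Ros1, a receptor tyrosine kinase gene, fell 6.59-fold (-2.72, SE 0.15), Ret fell 5.51-fold (-2.46, SE 0.16) and Gfra1 fell 3.79-fold (-1.92, SE 0.14), each with n = 4 per group. Gdnf, the ligand gene expressed in the mesenchyme, fell 3.32-fold (-1.73, SE 0.11). Six2, a transcription factor gene of nephron progenitors, fell 4.35-fold (-2.12, SE 0.41). Among genes that rose, Foxd1, which marks stromal progenitors, rose 2.09-fold (1.07, SE 0.14).

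Of 22180 genes, 6227 passed the threshold (28.1%), 3048 of them higher and 3179 lower in Grb2_cKO. Of these, 384 changed at least 2-fold, 271 higher and 113 lower. The values of the groups did not overlap for 6926 genes (31.2%, where chance gives 2.86%). The first principal component held 58.2% of the variance. The median log2 fold change of all genes was 0.0058, and no scaling tried moved it by more than 0.1.

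The groups also differed in sex-linked genes. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 9.94 to 10.1 in all 4 Grb2_cKO embryos and 9.94 in control replicate 3, and 4.09 to 4.24 in control replicates 1, 2 and 4. Xist, the RNA of the inactive X chromosome, was 12.2 to 12.8 in control replicates 1, 2 and 4, 5.39 in control replicate 3 and 4.95 to 6.03 in the Grb2_cKO embryos. With the Y-linked mean as a covariate 1213 of the 6227 genes passed the threshold the same way, 611 higher and 602 lower, and 6225 kept their sign. Among the 384 genes that changed at least 2-fold, 283 passed the same way. For the 5014 genes that lost the threshold, the median SE went from 0.0876 to 0.143 and the median size from 0.396 to 0.358. A call lost with the covariate therefore need not mean a smaller fold. The fold with the covariate rests on control replicate 3, the only control with high Y-linked values. That embryo was among the controls that chose these genes, so kept signs carry little weight. Changed genes outside X and Y were also chosen without it. Over these 5265 genes it lay at a median position of 0.137 between the controls (0) and Grb2_cKO (1), with quartiles of -0.022 to 0.302. As a single embryo it excludes nothing.

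**Figure D1:**
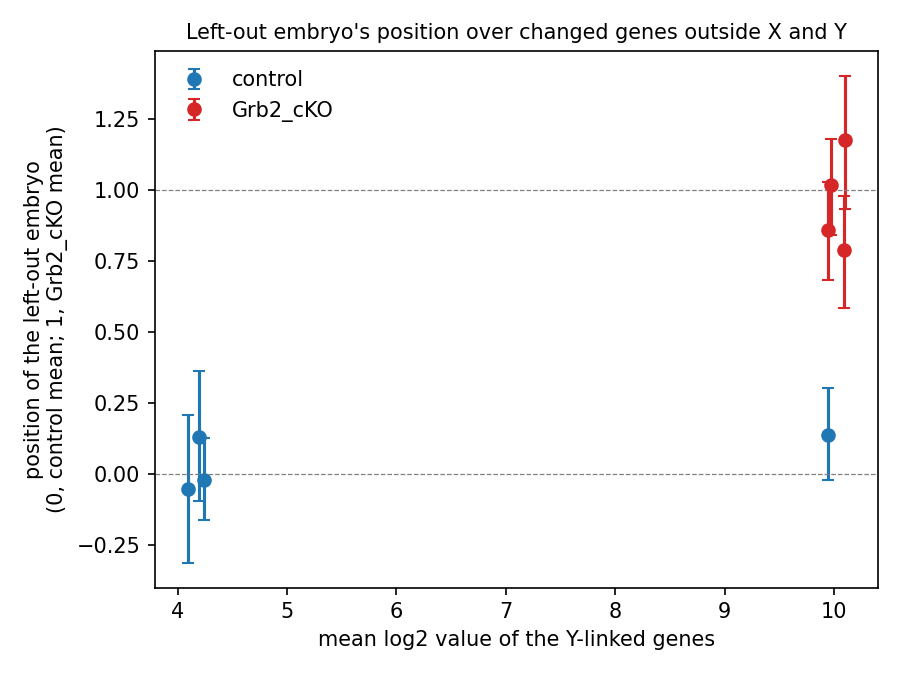
Median position of each embryo when left out of the model (vertical axis, 0 for the mean of the other controls and 1 for that of the other Grb2_cKO embryos, bars from the lower to the upper quartile over changed genes outside the X and Y chromosomes) against its mean log2 value of the Y-linked genes (horizontal axis). Control replicate 3 lay at 0.137 and the other controls at -0.053 to 0.129, and the Grb2_cKO embryos at 0.788 to 1.176, a measure chosen after seeing the data.

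**Figure D2:**
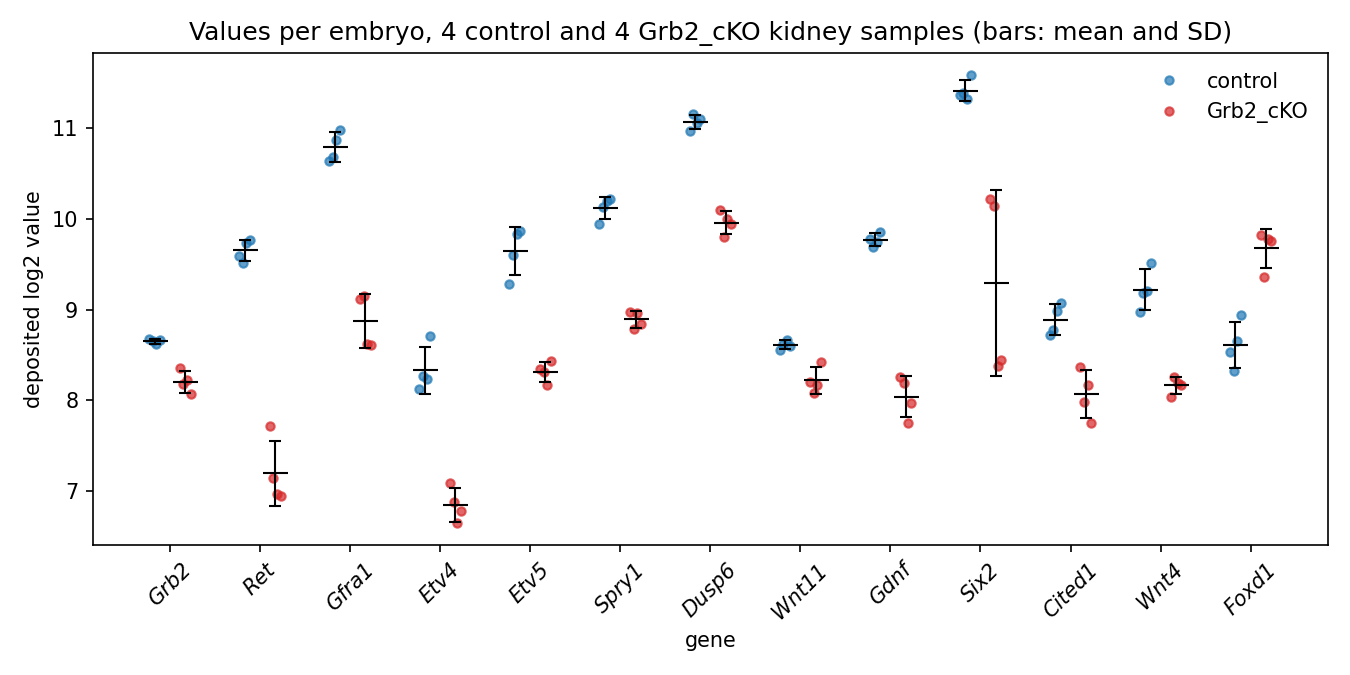
Deposited log2 values (vertical axis) of 13 genes (horizontal axis) in each of 4 control and 4 Grb2_cKO embryos, with the mean and SD of each group as bars. Ret lay at 9.65 ± 0.12 in controls and 7.19 ± 0.36 in Grb2_cKO, and Foxd1 at 8.61 ± 0.25 and 9.68 ± 0.21.

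In the ureteric tip list 16 of 20 measured genes fell, 1 rose and 3 did not pass (median log2 fold change -0.93). Adjusted over the list alone, 16 fell and 2 rose. The list was shifted down relative to other genes (camera adjusted p = 5.17e-10, and adjusted p = 0.163 with an estimated correlation). The 1 member that rose was Adamts18, at 1.61, named here after its values were seen. Of the 17 changed members, 12 passed with the Y-linked covariate.

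The list of genes that respond to RET and FGF receptors, which shares 7 members with the tip list, had 16 of 22 genes lower, 2 higher and 4 not passing (median -0.58). Adjusted over the list alone, 18 fell and 2 rose. Camera gave an adjusted p of 2.02e-09, and adjusted p = 0.163 with an estimated correlation. Etv4 and Etv5, transcription factor genes downstream of RET, fell by 1.49 (SE 0.14) and 1.33 (SE 0.13) on the log2 scale. Spry1 and Dusp6, feedback inhibitors of receptor and ERK signalling, fell by 1.23 (SE 0.08) and 1.11 (SE 0.08), and the transcription factor gene Myb fell by 1.02 (SE 0.08). Wnt11, a tip gene, fell by 0.39 (SE 0.08), and stood at -0.45 with the Y-linked covariate, past the threshold no longer (adjusted p = 0.094). Of the 18 changed members, 11 passed with that covariate. Components of the GRB2 complex and of the RAS and ERK pathway were not called as a list by camera (6 of 18 higher, 3 lower, 9 not passing, median 0.03, adjusted p = 0.159), while fry (adjusted p = 0.00078) and the exact permutation of the score (adjusted p = 0.0406) called the list higher. Adjusted over the list alone, 7 were higher and 3 lower, and 2 of the 9 changed members passed with the Y-linked covariate. Dok5, an adaptor gene, rose by 1.60 (SE 0.09), and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, rose by 0.60 (SE 0.06).

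The trunk and collecting duct list had 9 of 23 genes lower, 1 higher and 13 not passing (median -0.26, adjusted p = 0.00114, and adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, the counts were also 9 and 1. Calb1, a calcium-binding protein gene of the ureteric epithelium, fell 11.6-fold (-3.53, SE 0.32), and the epithelial genes Epcam and Ehf fell by 1.14 (SE 0.14) and 1.02 (SE 0.09). Wnt9b, an inducer of nephron formation, fell by 0.62 (SE 0.15), and stood at -0.51 with the Y-linked covariate, past the threshold no longer (adjusted p = 0.271), and 4 of the 10 changed members passed. Wnt7b stood at -0.06 (SE 0.10, adjusted p = 0.733). In the urothelium list 1 of 13 genes rose, Upk3b by 0.89 (SE 0.12), and 12 did not pass (median 0.10, adjusted p = 0.399). Adjusted over the list alone, 1 rose. Upk3b stood at 0.77 with the Y-linked covariate, past the threshold no longer (adjusted p = 0.059).

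Nephron progenitor genes fell together: 13 of 18 were lower, none of the other 5 passed, and the median was -0.93 (adjusted p = 1.18e-07, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, 14 fell. Beside Gdnf and Six2, Uncx fell by 1.29 (SE 0.09), Fgf20 by 0.99 (SE 0.10), Itga8 by 0.97 (SE 0.10) and Cited1 by 0.82 (SE 0.14). Six2 varied between the Grb2_cKO embryos, at 9.29 ± 1.02 against 11.4 ± 0.12 in controls. It stood at 10.2 and 10.1 in Grb2_cKO replicates 1 and 2, and at 8.37 and 8.44 in replicates 3 and 4. With the Y-linked covariate Six2 stood at -2.02 (adjusted p = 0.124) and Cited1 at -0.91 (adjusted p = 0.0516), neither past the threshold, and 8 of the 13 members passed. In the renal vesicle and early nephron list 11 of 19 genes fell, 1 rose and 7 did not pass (median -0.33, adjusted p = 0.000418, and adjusted p = 0.305 with an estimated correlation), with 12 lower and 2 higher adjusted over the list alone. Dkk1, an inhibitor of WNT signalling, fell by 1.32 (SE 0.10), Wnt4, which drives the transition to epithelium, by 1.06 (SE 0.11), Bmp2 by 0.80 (SE 0.11) and Lhx1 by 0.67 (SE 0.11). Of the 12 changed members 4 passed with the Y-linked covariate, and Lhx1, at -0.67, did not (adjusted p = 0.0693).

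WNT-responsive genes were lower in 10 of 16 cases and higher in 1, with 5 not passing (median -0.30, adjusted p = 0.00309, and adjusted p = 0.305 with an estimated correlation). The counts were the same adjusted over the list alone. Lgr5, a receptor and target gene of the pathway, fell by 0.84 (SE 0.11), but stood at -0.75 with the Y-linked covariate, past the threshold no longer (adjusted p = 0.0555), and 1 of the 11 changed members passed. Of the proliferation list 22 of 23 genes fell and 1 did not pass (median -0.51, adjusted p = 3.64e-13, and adjusted p = 0.218 with an estimated correlation). All 23 fell adjusted over the list alone, and 9 of the 22 passed with the Y-linked covariate. Rrm2, a subunit of ribonucleotide reductase, fell by 0.84 (SE 0.09), and Mcm6 and Mcm3, parts of the replicative helicase, by 0.75 (SE 0.09) and 0.74 (SE 0.09). In cholesterol synthesis 6 of 11 genes fell and 5 did not pass (median -0.32, adjusted p = 0.00038, and adjusted p = 0.218 with an estimated correlation), the same count as adjusted over the list alone. Sqle, which encodes squalene epoxidase, fell by 0.73 (SE 0.08), and Fdps by 0.68 (SE 0.09). With the Y-linked covariate 3 of the 6 passed, and the list median was -0.19.

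Stromal genes moved the other way. In the stroma list 15 of 23 genes rose, 1 fell and 7 did not pass (median 0.39, adjusted p = 4.86e-06, and adjusted p = 0.163 with an estimated correlation), and adjusted over the list alone 16 rose and 1 fell. Postn, an extracellular matrix protein gene, rose by 0.83 (SE 0.09), Smoc2 by 0.75 (SE 0.09), Ntn1 by 0.69 (SE 0.08) and Pdgfra, a receptor gene of mesenchymal cells, by 0.67 (SE 0.08). The matrix and fibrosis list, which shares 5 members with the stroma list, had 13 of 18 genes higher and 5 not passing (median 0.37, adjusted p = 2.7e-07, and adjusted p = 0.25 with an estimated correlation), with 15 higher adjusted over the list alone. Col5a1 rose by 0.72 (SE 0.09), Col1a1 by 0.66 (SE 0.09) and Tgfbi by 0.63 (SE 0.07). In the ureter smooth muscle list 5 of 14 genes rose and 9 did not pass (median 0.25, adjusted p = 0.00349, and adjusted p = 0.25 with an estimated correlation), as many as adjusted over the list alone. Tbx18, a transcription factor gene of ureteric mesenchyme, rose by 1.12 (SE 0.14), Myocd, an activator of smooth muscle genes, by 0.94 (SE 0.18) and Tshz3 by 0.81 (SE 0.06). Of the muscle protein genes, Smtn and Pln rose by 0.50 (SE 0.09) and 0.255 (SE 0.07). Myh11, Mylk and Des did not pass, at 0.03, -0.02 and -0.16 (adjusted p = 0.886, 0.939 and 0.342). Acta2 at 0.31 and Tagln at 0.48 did not pass either (adjusted p = 0.080 and 0.10). These genes except Smtn were named after their values were seen. With the Y-linked covariate the medians of the stroma, matrix and smooth muscle lists were 0.29, 0.32 and 0.12. Of their changed members 5 of 16, 2 of 13 and 2 of 5 passed with it. Among those that did not were Col5a1 at 0.52 (adjusted p = 0.0599), Col1a1 at 0.50 (0.0678) and Myocd at 0.63 (0.224).

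Podocyte genes rose: 12 of 17 were higher, over all genes and adjusted over the list alone, and 5 did not pass (median 0.52, adjusted p = 3.36e-05, and adjusted p = 0.253 with an estimated correlation). Thsd7a rose by 1.11 (SE 0.11), Podxl, a surface sialomucin gene, by 0.92 (SE 0.14), Sulf1 by 0.64 (SE 0.11) and Arhgap28 by 0.52 (SE 0.06), and 2 of the 12 passed with the Y-linked covariate, without Podxl at 0.84 (adjusted p = 0.072) and Sulf1 at 0.45 (0.172). In the proximal tubule list 2 of 22 genes rose, Dab2 by 0.64 (SE 0.07) and Spp2 by 0.27 (SE 0.08), and 20 did not pass, with 1 higher adjusted over the list alone (median 0.21, adjusted p = 0.04, and adjusted p = 0.58 with an estimated correlation). Without control replicate 4 that list missed the threshold (adjusted p = 0.164, median 0.13), as it did without control replicate 1 (0.0587, median 0.23). It also missed it without Grb2_cKO replicates 3 (0.223, median 0.09) and 4 (0.148, median 0.11) and with the Y-linked covariate (0.383, median 0.15). After quantile normalization (0.0581, median 0.21) and without the dim genes (0.0617, median 0.22) the list missed the threshold as well. Spp2 missed it with the Y-linked covariate, then at 0.22 (adjusted p = 0.374), as well as without Grb2_cKO replicate 1 (adjusted p = 0.0567) or 3 (0.0656) and without control replicate 4 (0.0555), while Dab2 passed with the covariate. Lrp2, which encodes the endocytic receptor megalin, stood at -0.10 (SE 0.25, adjusted p = 0.818). Camera did not call the loop and distal tubule list (3 of 18 higher, 2 lower, 13 not passing, the same adjusted over the list alone, median 0.14, adjusted p = 0.138), but called it without Grb2_cKO replicate 2 (median 0.23, adjusted p = 0.0105). Ptger3, a prostaglandin receptor gene, rose by 1.76 (SE 0.11), and 1 of the 5 changed members passed with the covariate.

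Markers of blood and vessel cells rose beside the stromal and podocyte genes. In the macrophage and leukocyte list 16 of 19 genes rose and 3 did not pass (median 0.64, adjusted p = 1.51e-09, and adjusted p = 0.163 with an estimated correlation), with 18 higher adjusted over the list alone. Fcer1g, an Fc receptor subunit gene, rose 3.76-fold (1.91, SE 0.15), C1qb of the complement system 3.19-fold (1.67, SE 0.15) and Adgre1, a macrophage surface receptor gene, 2.18-fold (1.12, SE 0.12). The erythroid list had 6 of 10 genes higher and 4 not passing (median 0.64, adjusted p = 0.000112, and adjusted p = 0.25 with an estimated correlation), with 7 higher adjusted over the list alone. Its mean was 6.24 to 6.63 in controls and 6.93 to 7.42 in Grb2_cKO. Slc4a1, the anion exchanger of red cells, rose by 1.35 (SE 0.16) and the embryonic globin genes Hba-x and Hbb-bh1 by 1.30 (SE 0.20) and 1.12 (SE 0.20). Of endothelial genes 10 of 19 rose and 9 did not pass (median 0.22, adjusted p = 2.92e-05, and adjusted p = 0.305 with an estimated correlation), with 11 higher adjusted over the list alone. Robo4 rose by 0.85 (SE 0.12) and Sox18 by 0.83 (SE 0.14). With the Y-linked covariate 7 of 16 macrophage, 1 of 6 erythroid and 0 of 10 endothelial members passed in limma. All of these changed members kept their sign, which carries little weight, since control replicate 3 was among the controls that chose them. Those not passing included Hba-x at 1.23 (adjusted p = 0.0728), Hbb-bh1 at 1.01 (0.117), Robo4 at 0.77 (0.0617) and Sox18 at 0.83 (0.0745).

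**Figure D3:**
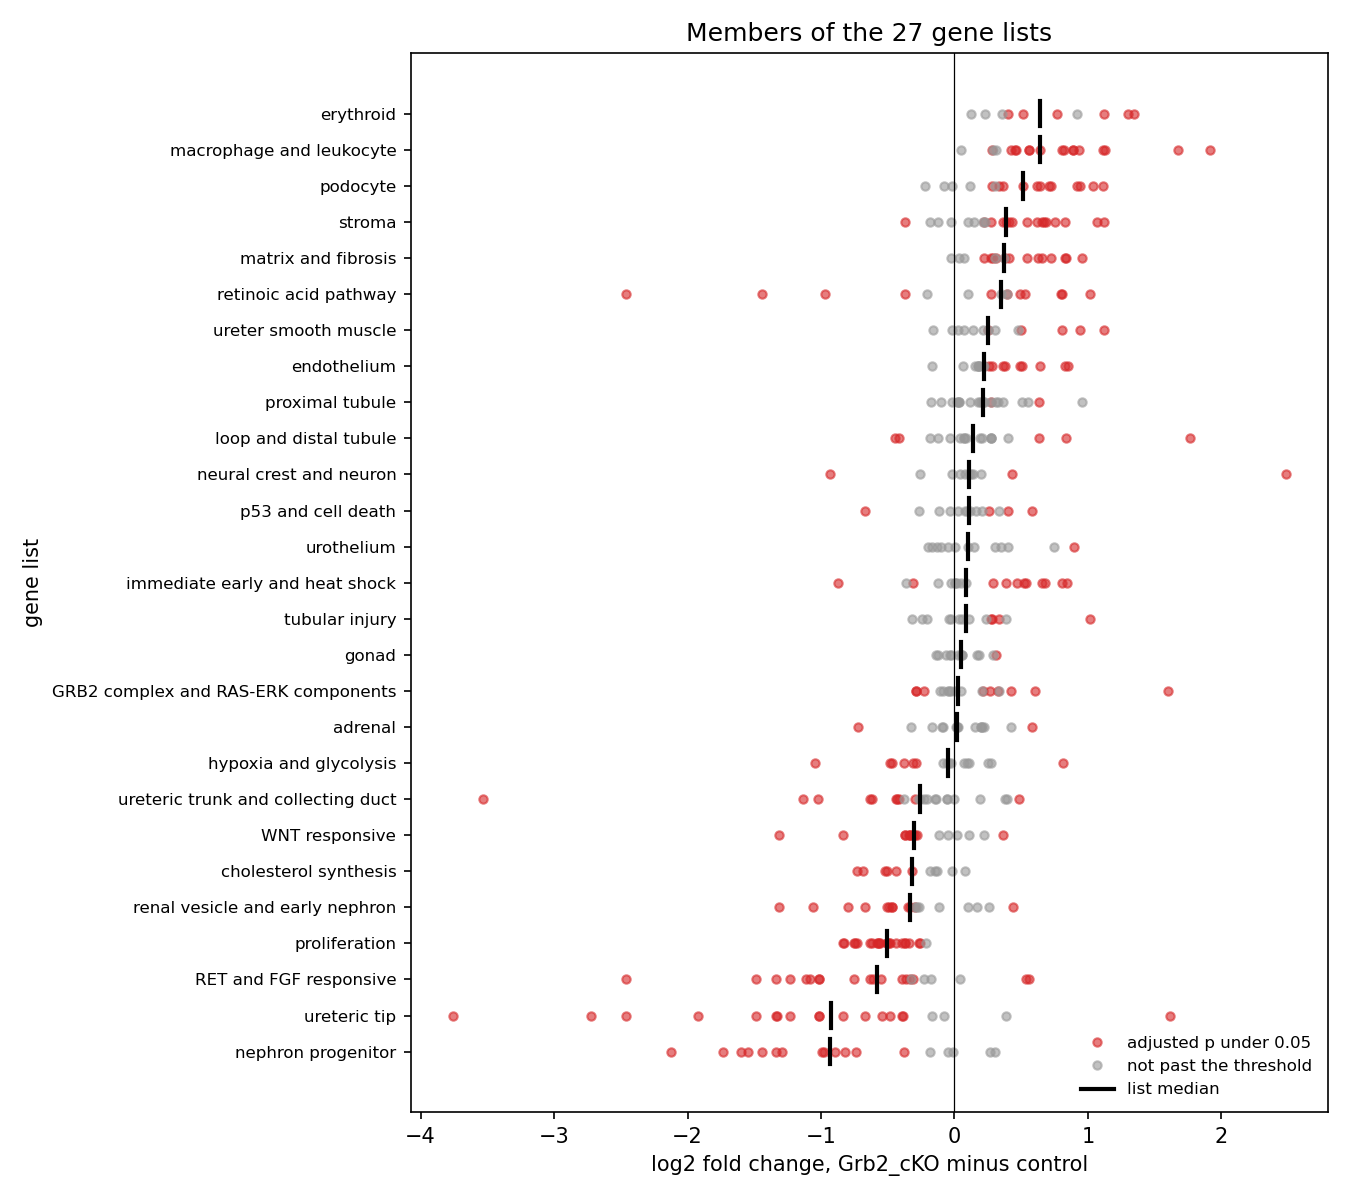
Log2 fold changes, Grb2_cKO minus control (horizontal axis), of the measured members of 27 gene lists (vertical axis), 1 point per gene, coloured by whether it passed an adjusted p of 0.05, with a black bar at each list's median. List medians ran from -0.93 in the nephron progenitor list to 0.64 in the erythroid list.

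Stress, hypoxia and retinoic acid genes went both ways. In the immediate early and heat shock list 9 of 19 genes rose, 2 fell and 8 did not pass, also adjusted over the list alone (median 0.09, adjusted p = 0.04, and adjusted p = 0.533 with an estimated correlation). Zfp36 rose by 0.84 (SE 0.12) and Jun by 0.68 (SE 0.08), and the heat shock gene Hsph1 fell by 0.87 (SE 0.12). The list missed the threshold without Grb2_cKO replicate 1 (adjusted p = 0.0678, median 0.09) or 4 (0.0682, median 0.16). It also missed it without control replicate 1 (0.0876, median 0.11) or 2 (0.0698, median 0.06) and with the Y-linked covariate (0.0896, median 0.13). After quantile normalization (0.0581, median 0.10) and without the dim genes (0.0617, median 0.29) the list missed the threshold as well. In the hypoxia and glycolysis list 6 of 16 genes fell, 1 rose and 9 did not pass (median -0.05, camera adjusted p = 0.197, fry 0.000804 and exact permutation 0.0406), with 6 lower and 3 higher adjusted over the list alone. Hk2, which encodes hexokinase 2, fell by 1.04 (SE 0.09) and Ndrg1 rose by 0.81 (SE 0.13). In the retinoic acid list 7 of 15 genes rose, 4 fell and 4 did not pass, with 8 and 4 adjusted over the list alone. Its median was 0.35 and its mean -0.02 (adjusted p = 0.27). The retinaldehyde dehydrogenase genes Aldh1a3 and Aldh1a1 fell by 1.44 (SE 0.10) and 0.97 (SE 0.14), and Crabp1, a retinoic acid binding protein gene, rose by 1.02 (SE 0.10). The Y-linked covariate left 2 of 11 changed immediate early, 2 of 7 hypoxia and 3 of 11 retinoic acid members past the threshold, without Zfp36 at 0.72 (adjusted p = 0.0731), Ndrg1 at 0.75 (0.089) and Aldh1a1 at -0.88 (0.0675).

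Camera did not call the remaining lists. Of tubular injury genes 4 of 14 rose and 10 did not pass (median 0.08, camera adjusted p = 0.184, fry 0.0169 and exact permutation 0.0406), with 6 higher and 1 lower adjusted over the list alone, and Hmox1, which encodes heme oxygenase 1, rose by 1.02 (SE 0.10). Of the p53 and cell death list 3 of 14 rose, 1 fell and 10 did not pass, also adjusted over the list alone (median 0.11, adjusted p = 0.369). Of neural crest and neuron genes 2 of 11 rose, 1 fell and 8 did not pass, also adjusted over the list alone (median 0.11, camera adjusted p = 0.316, fry 0.0169 and exact permutation 0.0406). In the adrenal list 1 of 16 genes rose, 1 fell and 14 did not pass, also adjusted over the list alone (median 0.02, adjusted p = 0.556). In the gonad list 1 of 13 rose, Lhx9 by 0.31 (SE 0.09), 12 did not pass, and none passed adjusted over the list alone (median 0.05, adjusted p = 0.505). Lhx9 missed the threshold without control replicate 1 (adjusted p = 0.0687), 2 (0.053) or 3 (0.0702) and without Grb2_cKO replicate 1 (0.0531) or 2 (0.0642). The Y-linked covariate left 1 of 4 changed tubular injury, 1 of 4 p53, 2 of 3 neural crest, 0 of 2 adrenal and 0 of 1 gonad members past the threshold, with Lhx9 at 0.40 (adjusted p = 0.161).

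The other genes with the largest rises were Stmn2, a microtubule regulator of neurons, at 5.59-fold (2.48, SE 0.16), Sult1e1, an estrogen sulfotransferase gene, at 5.25-fold (2.39, SE 0.33), the cadherin gene Cdh9 at 4.85-fold (2.28, SE 0.12), the adhesion gene Ncam2 at 4.62-fold (2.21, SE 0.18) and Nkain2 at 4.41-fold (2.14, SE 0.15). Ms4a7, a gene of macrophages, rose 4.20-fold (2.07, SE 0.18), and Zfp703, Parm1, Creb5 and Fxyd1 rose by 1.90 to 1.95 on the log2 scale. Vsnl1, a calcium sensor gene, fell by 1.97 (SE 0.24), the keratin gene Krt23 by 1.90 (SE 0.16), Rprm by 1.76 (SE 0.23), Rasef by 1.75 (SE 0.23) and Rabggtb by 1.64 (SE 0.18). With the Y-linked covariate 10 of the 12 largest rises and 11 of the 12 largest falls passed. With the erythroid covariate 5 of these rises and 9 of these falls did, and with control replicate 3 as the only control, chosen after seeing the data, 10 and 7. The exceptions with the Y-linked covariate were the Y-linked Kdm5d, then at 0.05 (adjusted p = 0.886), Sult1e1 at 2.02 (0.0586) and Six2 at -2.02 (0.124). Kdm5d is part of the Y-linked mean, so its loss was fixed by construction.

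Of the 27 lists, camera with its preset correlation called 17, 9 higher and 8 lower. With an estimated correlation camera called 0 at an adjusted p of 0.05, 6 at an unadjusted p under 0.05, with 0.163 as the smallest adjusted p. Fry called 20 and the exact permutation of list scores 19, each of these 19 at the smallest p of 0.0286 (adjusted p = 0.0406). Neither test compares a list with other genes, of which 28.1% passed the threshold. Their counts therefore do not show shifts particular to these lists.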

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

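Of the tests in this part, the count over other splits of the embryos was planned, as was the Y-linked covariate, but its use to weigh embryo sex, the tests of admixture and of developmental delay, and the position of left-out embryos were chosen only after the results were seen.

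Among 298 groups of 4 values (named genes, list means and array medians), 16 held an embryo far from the other 3, where chance gives about 1 in 20, or 14.9. In control replicate 3 these were Eif2s3y at 9.95 (others 4.21 to 4.37), Kdm5d at 9.70 (4.16 to 4.22), Uty at 10.17 (3.80 to 4.36), Xist at 5.39 (12.2 to 12.8) and Sult1e1 at 5.16 (4.65 to 4.72). In control replicate 1 they were Calb1 at 11.71, Pik3r1 at 11.05 and Rasef at 8.48, each above the others. Nkain2 was low at 6.80 in control replicate 2, Krt18 was low at 9.68 in control replicate 4, and the mean of the GRB2 complex and RAS-ERK list was high there at 9.27 (others 9.21 to 9.22). In Grb2_cKO embryos Dab2 was low at 11.02 in replicate 1, Foxd1 at 9.36 and Klf6 at 10.75 were low in replicate 2, and Cd44 at 7.10 and Tgfbi at 12.75 were high in replicate 4. No explanation was tested for these.

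A signal was also present in probe sets outside the comparison. Of 17824 probe sets without a single gene symbol, 1978 passed the threshold, 828 higher and 1150 lower (11.1%, against 22.1% of the named probe sets).

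The first pattern is the number of genes that differed. In limma the real split of the 8 embryos into 4 and 4 gave 6227 genes, the most of the 35 splits. The highest other gave 0 (2577 at an unadjusted p under 0.05, against 8429). With 35 splits the real one could rank no better than 1 in 35. Every other split mixed the genotypes within each group, so any genotype difference widened the spread within groups and lowered the count. These counts therefore cannot exclude chance, and they do not separate genotype from sex. For embryo sex as the whole cause, 1213 genes stayed past the threshold the same way with the Y-linked covariate. Their median SE went from 0.0879 to 0.141 while their median size went from 0.739 to 0.736. The fold with the covariate rests on control replicate 3, the only control with high Y-linked values. For Ret it was -2.536 with the covariate and -2.544 against that embryo alone. The 1213 genes speak against sex as the whole cause only if that embryo is typical of controls of its sex. For the other 5014 genes the fold change with the covariate was at the median 0.879 of that without it (quartiles 0.751 to 1.029). Their median size went from 0.396 to 0.358 and the median SE from 0.0876 to 0.143. How many of these calls ended through the wider error was not counted. For these genes genotype and sex cannot be told apart, since only control replicate 3 separates the genotype from the sex. Left out of the model, that embryo lay at a median position of 0.137 between the controls (0) and Grb2_cKO (1) over changed genes outside X and Y (quartiles -0.022 to 0.302), against -0.053 to 0.129 for the other controls and 0.788 to 1.176 for Grb2_cKO, which excludes nothing as a single embryo. A contribution of sex may therefore remain in any gene of the report, whether or not it passed with the covariate.

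The second pattern is the fall of tip and progenitor genes beside a rise of stromal and podocyte genes. RNA of blood or neighbouring tissue would dilute every kidney cell type and a delay of development would lower genes that come on late, while the podocyte list score rose by 0.488 without overlap between the groups. That rise is part of the pattern itself, and the list was chosen for the admixture test, in place of the stroma list (0.392), with both values known, so it decides neither explanation. Scores of the late proximal tubule and loop and distal tubule lists stood at 0.234 and 0.218 with overlapping groups, the erythroid score rose by 0.708, and the adrenal and gonad scores, of tissue beside the kidney, stood at 0.042 and 0.059 with overlapping groups. Admixture, a delay, and a smaller share of tip and progenitor cells after loss of Grb2 may each contribute, and cannot be told apart from a change per cell here.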

How the results depend on the processing

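Using control replicate 3 as the only control was chosen after seeing the data; the other alternatives here were planned. No paired analysis was possible because the replicate numbers only follow the order of the records. Quantile normalization, median centring, leaving out dim genes, probe-set means, a trended spread, and array weights kept the counts of changed genes within 1.5 times and the direction and call of Grb2, and testing all probe sets kept those counts within 1.5 times. With the Y-linked covariate 1246 genes passed (633 higher, 613 lower) and the Grb2 log2 fold change was -0.40, no longer past the threshold (adjusted p = 0.10). With the erythroid covariate, whose values do not overlap between the groups, 143 passed (57 higher, 86 lower), Grb2 was -0.57 and no longer past it (adjusted p = 0.167), and the median SE of the 6090 genes that lost the threshold went from 0.0874 to 0.209 while their median size went from 0.438 to 0.430. With control replicate 3 as the only control, assumed to vary like the other group, 285 passed (165 higher, 120 lower) and Grb2 was -0.41, no longer past it (adjusted p = 0.164). The adjusted p of Grb2 over these and the other alternatives ran from 0.00066 to 0.167. An unadjusted p of 0.05 with a 2-fold change gave 387 genes (274 higher, 113 lower), and an adjusted p of 0.05 with a 1.5-fold change gave 1789 (1062 higher, 727 lower), by construction. Camera with an estimated correlation called 0 lists and fry for mixed changes 26. Quantile normalization and leaving out dim genes gave 15 called lists each instead of 17, both without the proximal tubule and immediate early lists (adjusted p = 0.0581 and 0.0617). Leaving out 1 embryo at a time gave 4894 to 5955 changed genes, 2364 to 2976 higher and 2530 to 2979 lower, 15 to 18 lists, and a Grb2 log2 fold change of -0.50 to -0.40. Of the 119 named genes past the threshold, 69 stayed past it with the Y-linked covariate and 30 with the erythroid covariate. Signs were kept by 117 and 119 of them, and by 118 with control replicate 3 as the only control. Signs kept with the Y-linked covariate or against that embryo carry little weight, since it was among the controls that chose the genes.

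Values whose direction turned, by the sign of a gene or the direction of a list test, were these, and the cause was not tested. With the Y-linked covariate Eif2s3y was -0.049, Xist 0.15 and the urothelium median -0.0015. Eif2s3y is part of the Y-linked mean, so its small value there was fixed by construction. With the erythroid covariate Lrp2 was 1.32. Camera's direction then turned to down for the gonad, immediate early and retinoic acid lists. Their medians stayed positive, at 0.0035, 0.054 and 0.023 (0.051, 0.088 and 0.352 in the main model). With control replicate 3 as the only control Xist was 0.048 and the urothelium median -0.013. Without the dim genes camera's direction turned to down for the adrenal list, while its median stayed positive at 0.0095 (0.022 in the main model). Lrp2, not past the threshold, was -0.28 (lowest) without Grb2_cKO replicate 3, 0.064 (highest) without Grb2_cKO replicate 1, 0.0019 without Grb2_cKO replicate 2 and 0.0008 without control replicate 2. Without detection calls, what signal over background limits was not analysed here.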

Other observations

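The gene classes and tests of this part were chosen only after the results were seen, the class lists included, and the genes named here were chosen after their values were seen. The test of small RNA recovery first rested on microRNA genes alone, and the other small non-coding RNA genes were added after those values were known, which left the question open where the first test had argued against it.

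Genes of the imprinted domain between Dlk1 and Dio3 rose together. Of 55 measured genes of the domain 46 rose and none fell, with a median log2 fold change of 1.03 (exact permutation p = 0.0286, adjusted over 10 classes 0.0409, and adjusted p = 0.0611 for camera with an estimated correlation). Among them 38 of 43 microRNA genes rose, with a median of 1.07, while 440 microRNA genes outside the domain had a median of -0.0058 (quartiles -0.187 to 0.169). Dlk1, which encodes a membrane protein related to NOTCH ligands, rose by 1.48 (SE 0.12), the non-coding RNA genes Rian and Meg3 by 0.88 (SE 0.11) and 0.28 (SE 0.08), and Dio3 stood at -0.03 (SE 0.09, adjusted p = 0.866). With the Y-linked covariate 19 of the 46 changed genes passed, without Meg3 at 0.23 (adjusted p = 0.374). All 46 kept their sign, which carries little weight, since control replicate 3 was among the controls that chose them. The domain also holds 6 measured genes annotated as small nucleolar RNA (snoRNA), of which 5 rose (median 0.85, range 0.17 to 1.54) and 2 of the 5 passed with that covariate.

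Genes of ribosome production fell. Of a list of 28 ribosome biogenesis genes 25 fell and none rose (median -0.50, exact permutation p = 0.0286, and adjusted p = 0.059 for camera with an estimated correlation), among them the nucleolar protein genes Ncl by 0.82 (SE 0.10), Dkc1 by 0.69 (SE 0.11) and Nop56 by 0.67 (SE 0.07). Of 86 genes whose names start with Rps or Rpl and a digit, 35 fell and 2 rose (median -0.22, and adjusted p = 0.0611 for camera with an estimated correlation). These names are mainly given to ribosomal protein genes, but kinase genes and pseudogenes with such names were not removed. Of 16 genes on a list of MYC and translation supply 13 fell (median -0.73, and adjusted p = 0.0611 for camera with an estimated correlation), Mycn by 1.13 (SE 0.10), while Myc stood at -0.21 (SE 0.11, adjusted p = 0.21). Under the Y-linked covariate 10 of 25 changed ribosome biogenesis genes, 8 of 37 genes with Rps or Rpl names and 9 of 13 genes of MYC and translation supply passed, and Dkc1, at -0.73, did not (adjusted p = 0.0501). Snhg genes, many of which host snoRNAs in their introns, fell in 10 of 15 cases and rose in 2 (median -0.44, and adjusted p = 0.059 for camera with an estimated correlation, 3 of the 12 passing with that covariate). The MYC list holds Gldc, whose fold had been seen when the list was written.

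The third pattern is a fall of snoRNA genes outside the domain, where of 73 genes with Snora or Snord names 52 fell and 1 rose (median -0.73, exact permutation p = 0.0286, and adjusted p = 0.0611 for camera with an estimated correlation), and 25 of the 53 passed with the Y-linked covariate. By annotation instead of name, a choice made after seeing the data, the counts were 52 and 1 of 75 outside the domain (median -0.705), and 52 and 6 of 81 with the domain (median -0.62). A lower recovery of small RNAs would lower other small non-coding RNA genes as well, and 10 of these had a median of -0.20 (quartiles -0.46 to -0.015), with Rny3 at -1.13 and Rn7sk at -0.06. The 119 microRNA genes outside the domain and above the lower quartile of the snoRNA genes had a median of -0.0039. Of the 6 snoRNA genes of the domain 5 rose. Both go against a general loss, but microRNA probe sets may read the precursor transcripts. The 6 domain genes lie in a region where 46 of 55 measured genes rose. Recovery therefore cannot be told apart from lower expression. The ribosome biogenesis score fell by 0.538 without overlap between the groups, and a shared fall of ribosome production may be one explanation, which these values do not separate from a technical loss or, as the tip, progenitor and proliferation lists fell too (22 of 23 genes lower in the last), from a smaller share of cycling progenitor cells, for which no test was made.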
